A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

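Chromatin from budding yeast (Saccharomyces cerevisiae) grown in rich medium was immunoprecipitated through a FLAG tag on 1 of 3 proteins, and the recovered DNA was hybridized against input DNA on two-colour arrays (ChIP-chip). The tagged proteins were Isw1, the ATPase of the Isw1a and Isw1b remodelers, Ioc3, a subunit of Isw1a, and Ioc4, a subunit of Isw1b. Each was measured in wild-type (WT) cells and in cells of a strain labelled set2, after SET2, the gene of the histone H3 lysine 36 methyltransferase. The labels call the 3 arrays of each of the 6 groups biological replicates, and nothing in the files pairs a replicate number in 1 group with that in another. IP DNA carried Cy5 (red) and input DNA Cy3 (green).

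The scanner files hold spot signals in intensity units which the authors made with Agilent Feature Extraction 10.5.1.1, with a background from negative controls, spatial and multiplicative detrending and dye normalization, per the file headers. They also hold raw mean signals and local background medians, in intensity units without correction, per the file headers. Flags in another unit, 0 or 1 per spot, mark spots well above background, per the file headers. The deposited value table holds log2 ratios of IP over input that the authors normalized in a way the labels do not state, and the submitters' processing notes name R 2.12.1. Scanner files were at hand for the 12 Ioc3 and Ioc4 arrays (41775 probes each, median spacing 257 bp, median length 60 bases) and for the 3 set2 Isw1 arrays. The 6 Isw1 arrays are of another design (60647 probes), and the 3 WT Isw1 arrays had values only in the table, so the Isw1 comparison used the table for both groups. Probe positions are those of the file headers on the sacCer1 build, and 5658 of the 5679 genes named on the Ioc array were matched to a locus tag of the R64 annotation, which was used for gene names only.

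The labels of the 2 sources contradict each other for Ioc3 and Ioc4. In the deposited log2 table, 12 of the 12 Ioc3 and Ioc4 columns correlated best, with r from 0.82 to 0.99 across probes, with the scanner array of the other protein of the same background and replicate number, while r with the array of their own label was 0.28 to 0.44. Probes are not independent replicates, and no test was attached to these r. The main analysis follows the scanner files, whose labels are used throughout as "labelled Ioc4" and "labelled Ioc3". Every sign that contrasts both proteins, and the protein each set2 difference belongs to, would change places under the labels of the table. The set2 Isw1 columns matched their own scanner arrays with r of 0.99.

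For the Ioc arrays the log2 ratio of the processed red over green signal was taken for each probe and each array was centred on its median; the Isw1 table values were centred in the same way. Control spots were left out. An ORF value is the mean over probes at or past the gene start, with at least 3 probes, and a promoter value is the mean over probes up to 500 bp before it, with at least 1 probe. The array files give no ORF ends, so that the span of a gene is that of its probes. For genes with a span of at least 1000 bp the ORF was divided in 3 equal parts, called the first, middle and last part, and the mean of the middle part minus the promoter gave 1 value per array. SET2 was left out of these features, since its input signal was low in the strains labelled set2. That signal was between 0.119% and 20.0% of the array median.

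Differences per ORF and promoter were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p threshold 0.05), with all 12 Ioc arrays in 1 fit and the 6 Isw1 arrays in another. The comparisons fitted were 5: set2 against WT for each of the 3 labels, the arrays labelled Ioc4 against those labelled Ioc3 in WT, and the difference between the set2 effects of both. Values per array were compared with two-sided exact permutation tests. With 3 arrays against 3 such an exact permutation test cannot go below p = 0.1. The set2 effects of both labels were compared by permuting the genotype within each label, where the smallest p is 0.005. The 16 gene lists were fixed beforehand and tested with camera from limma, with a preset correlation of 0.01 and again with an estimated one, which makes 80 tests of a list in a comparison. Camera p was adjusted over the 16 lists of each comparison. Named genes were taken by a rule: among ORFs past the threshold whose arrays did not overlap between groups, the 8 with the largest positive and the 8 with the largest negative difference, 5 and 5 for promoters, up to 4 members of each gene list with the largest difference, and in every case ISW1, CHD1, IOC2, IOC3, IOC4, FLO8, STE11 and PMA1. The groups, comparisons, tests, lists and this rule were set before the data were examined.

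Scan sessions were read from the scanner files. Session 1 held the 3 WT arrays and 1 set2 array labelled Ioc4, session 2 held 1 set2 array labelled Ioc4 and 1 WT array labelled Ioc3, session 4 held 2 WT and 2 set2 arrays labelled Ioc3, and sessions 3 and 5 held 1 set2 array each. The 3 set2 Isw1 arrays shared session 6. The session of the WT Isw1 arrays is not known, so for Isw1 the batch and the genotype cannot be told apart. With the session as a fixed block, set2 against WT labelled Ioc4 rests on set2 array 1 alone, and labelled Ioc3 on the arrays of session 4. That block links both labels in WT only through set2 arrays 1 and 2 labelled Ioc4 and WT array 1 labelled Ioc3.

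The alternatives were normexp background correction (offset 50) with and without loess, the deposited table, scaling by the median absolute deviation (MAD), no centring, quantile normalization for the Isw1 arrays, input probes above background only, medians over probes, other probe minimums, the replicate number or the scan session as a block, limma with trend and robust settings, only the 2 groups compared, an estimated correlation for the lists, and leaving out each array in turn. Added after the data were seen were a correction for probe GC content, leaving out 3 doubted arrays, the fits within a scan session, alternatives for the difference of the set2 effects in the middle part minus the promoter, alternatives for the gene lists other than the estimated correlation and the replicate block, and those for the quartiles of ORF length and WT Isw1 level. The number of arrays limits the precision. The median SE of an ORF difference was 0.16 log2 on the Ioc arrays and 0.06 on the Isw1 arrays; for promoters it was 0.32 and 0.11.

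The functions used were tested on simulated data with known changes. For a log2 change of 1, limma recovered 79.7% of changed ORFs for set2 against WT labelled Ioc4 (4478 ORFs), 82.1% labelled Ioc3 and 100% for Isw1 (4502 ORFs). For a change of 0.5 the shares were 14.5%, 25.7% and 97.4%. Promoters had less power on the Ioc arrays, where 3.57% of changes of 1 were recovered labelled Ioc4, against 95.6% on the Isw1 arrays. Camera called a shifted list in 20 of 20 draws and an unshifted list in 2 of 300 tests. Genes were drawn without correlation between them, so this says nothing of false calls for lists whose members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.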

Results

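The data are log2 ratios of FLAG IP over input DNA along the yeast genome for 18 arrays, 3 for each of 6 groups: Isw1, Ioc4 and Ioc3, each in WT cells and in cells of strains labelled set2. Median signals on the 15 arrays with scanner files ran from 1073 to 1289 in the input and from 952 to 1297 in the IP. At least 99.8% of input spots were well above background on each of these arrays. In the IP the share was at least 97.1% except on the WT array 2 labelled Ioc3 (73.5%) and the set2 array 2 labelled Ioc4 (83.9%). Neighbouring probes correlated at r of 0.85 to 0.86 on the set2 Isw1 arrays. Labelled Ioc4, r was 0.22 to 0.48 in WT and 0.07 to 0.29 in set2. Labelled Ioc3, it was 0.08 to 0.18 in WT and 0.07 to 0.10 in set2, so that signal along the genome was weakly coherent there. The labels Ioc3 and Ioc4 are those of the scanner files and change places in the deposited table, where 12 of 12 columns match the array of the other protein.

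The first comparison asked whether a loss of SET2, which encodes the histone H3 lysine 36 methyltransferase, shows in the DNA. Input signal at SET2 was near the array median in WT cells, at -0.09 ± 0.05 log2 (SD, n = 3) labelled Ioc4 and -0.09 ± 0.06 labelled Ioc3. It was -6.53 ± 2.38 and -4.46 ± 1.91 on the corresponding set2 arrays and -9.59 ± 0.16 on the set2 Isw1 arrays. The neighbouring genes ASG7 and ERG20 stayed within 0.18 of the array median on each array. The difference over the 12 Ioc arrays was -5.40 (exact permutation p = 0.00216, two-sided). Within each label it was -6.43 for Ioc4 and -4.37 for Ioc3 (exact permutation p = 0.1 each, the smallest that 3 against 3 arrays allow). With raw in place of processed input signal the differences were -4.57, -5.30 and -3.83. The set2 array 3 labelled Ioc3 kept the most SET2 signal, at -2.32 or 20.0% of the array median, against 2.98% and 1.57% on arrays 1 and 2. Whether it is a pure set2 sample is thus in doubt and was not tested. The set2 array 3 labelled Ioc4 kept 5.21%, against 0.195% and 1.26% on arrays 1 and 2 of that label. Input signal also differed at HIS3 (0.18 in WT labelled Ioc3, -4.79 in WT labelled Ioc4 and -4.43 in set2 labelled Ioc3) and at URA3 (0.60 in WT labelled Ioc4, -7.26 in WT labelled Ioc3 and -1.28 in set2 labelled Ioc4). The set2 comparisons of both labels, and that between labels, thus carry differences at loci other than SET2, whose effect was not tested.

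**Figure D1:**
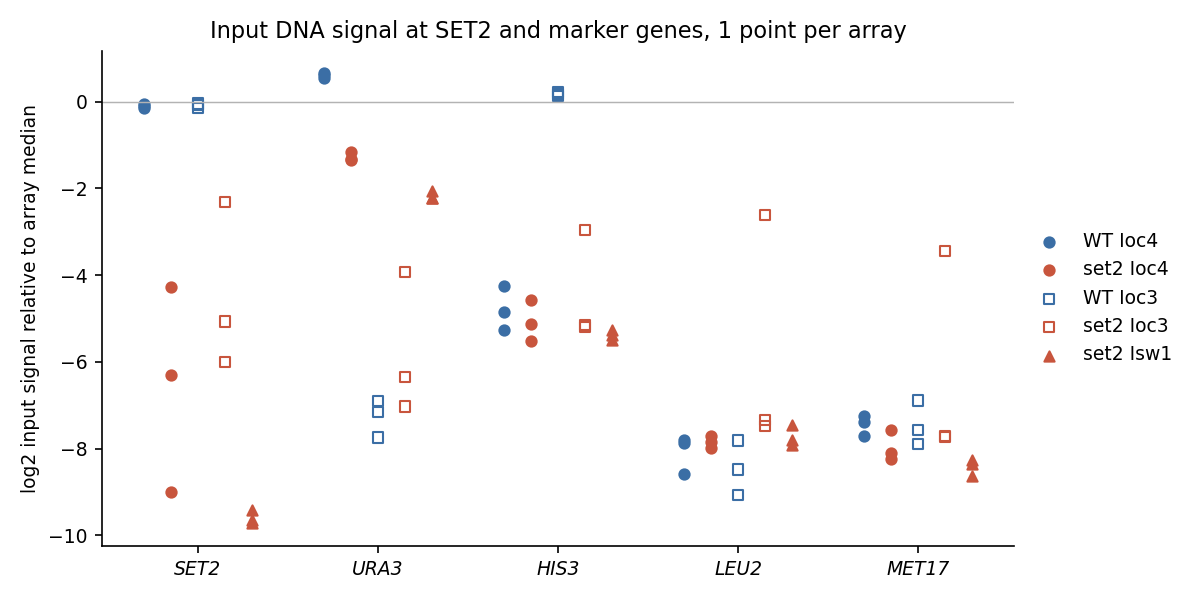
Log2 input signal relative to the array median at SET2 and at 4 marker genes, with 1 point per array (filled circles labelled Ioc4, open squares labelled Ioc3, triangles set2 Isw1, blue WT, red set2). SET2 lies near 0 in WT and between -9.72 and -2.32 on the set2 arrays.

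The Isw1 comparison asked where the remodeler ATPase sits on genes with and without Set2. In WT cells Isw1 was depleted over promoters and enriched inside genes of at least 1000 bp: the mean over 2710 genes was -0.31 ± 0.05 log2 (SD, n = 3) over promoters and 0.17 ± 0.02 over the middle part of the ORF. In set2 cells the profile was flatter, with -0.13 ± 0.04 over promoters and 0.10 ± 0.01 over the middle part. The set2 minus WT difference was 0.19 over promoters, 0.10 over the first part, -0.07 over the middle part and -0.05 over the last part. The middle part minus the promoter was 0.48 ± 0.06 in WT and 0.23 ± 0.05 in set2, a difference of -0.25 with an SE of 0.05. It was lower in 3 of 3 set2 arrays than in any WT array (exact permutation p = 0.1 for each region, two-sided, the smallest that 3 against 3 arrays allow). The scan session of the WT Isw1 arrays is unknown, so batch and genotype cannot be told apart.

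**Figure D2:**
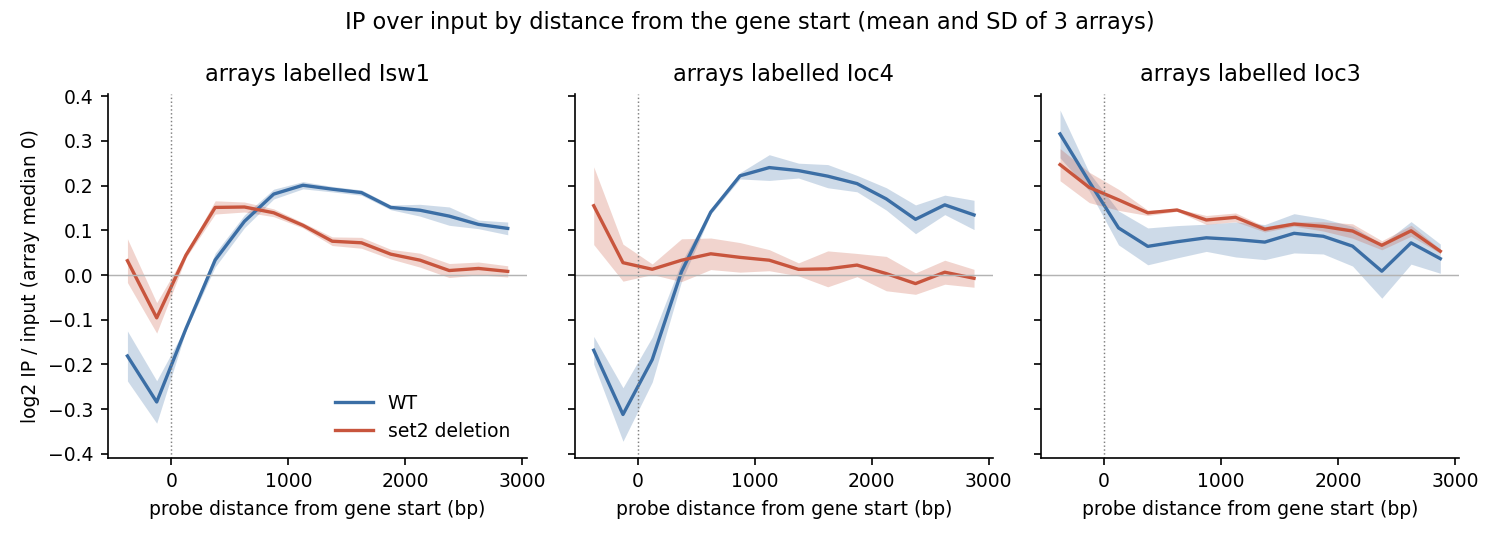
Mean log2 IP over input (line) and SD of 3 arrays (band) in windows of 250 bp by probe distance from the gene start, WT in blue and set2 in red, for the arrays labelled Isw1, Ioc4 and Ioc3. From 1000 to 1250 bp inside genes, Isw1 was 0.20 in WT and 0.11 in set2, and the arrays labelled Ioc4 were 0.24 in WT and 0.03 in set2.

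Among the single ORFs named by rule, the largest Isw1 rises in set2 were over PAU8, a seripauperin gene, ADH1, the main alcohol dehydrogenase, and RRN5 (0.74), a factor of RNA polymerase I transcription. ADH1 (chromosome 15, probes 159700 to 160446) was 2.42 ± 0.04 log2 in set2 and 1.68 ± 0.25 in WT, a difference of 0.74 with an SE of 0.10 (limma adjusted p = 0.00374). PMA1, the plasma membrane proton pump (chromosome 7, probes 480024 to 482570) was 2.49 ± 0.07 and 1.81 ± 0.22 (limma adjusted p = 0.00374). PAU8 differed by 0.82 with an SE of 0.18 (adjusted p = 0.0183, but 0.0719 without WT array 3, 0.0728 without set2 array 1 and 0.0512 without set2 array 2). Isw1 fell most over LEU1, the isopropylmalate isomerase of leucine synthesis (chromosome 7, probes 476389 to 478664), from 0.87 ± 0.09 in WT to -0.03 ± 0.05 in set2. That difference of -0.90 had an SE of 0.06 (limma adjusted p = 0.000119). Isw1 also fell over OAC1, a mitochondrial carboxylate carrier (-0.53, adjusted p = 0.00125), and over BAT1, the mitochondrial branched-chain aminotransferase (-0.49, adjusted p = 0.00546). Other large rises were over YKR041W (0.69) and the glycolytic and fermentation genes TDH3 (0.65), PDC1 (0.63) and ENO2 (0.60). With quantile normalization ADH1 (0.21, adjusted p = 0.171), PMA1 (0.11, 0.33), TDH3 (0.14, 0.427), PDC1 (0.11, 0.492) and ENO2 (0.098, 0.328) lost the call. Other large falls were over RIE1 (-0.43), ROM1 (-0.37), PET111 (-0.36), LOS1 (-0.35) and RCY1 (-0.35). IOC2, which encodes an Isw1b subunit, rose by 0.38 (adjusted p = 0.0202, but 0.0594 without WT array 3, 0.0521 to 0.0752 without each set2 array, and 0.516 with medians over probes). Of the 46 ORFs named in any part of this comparison that passed, 23 lost the call and 4 turned with quantile normalization. Calls lost numbered 11, 1 and 21 without WT arrays 1, 2 and 3, and 22, 26 and 14 without set2 arrays 1, 2 and 3. ISW1 (-0.15, adjusted p = 0.112), CHD1 (-0.12, 0.106), IOC3 (-0.15, 0.0824), IOC4 (-0.01, 0.912), FLO8 (0.13, 0.156) and STE11 (-0.05, 0.513) did not pass the test.

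**Figure D3:**
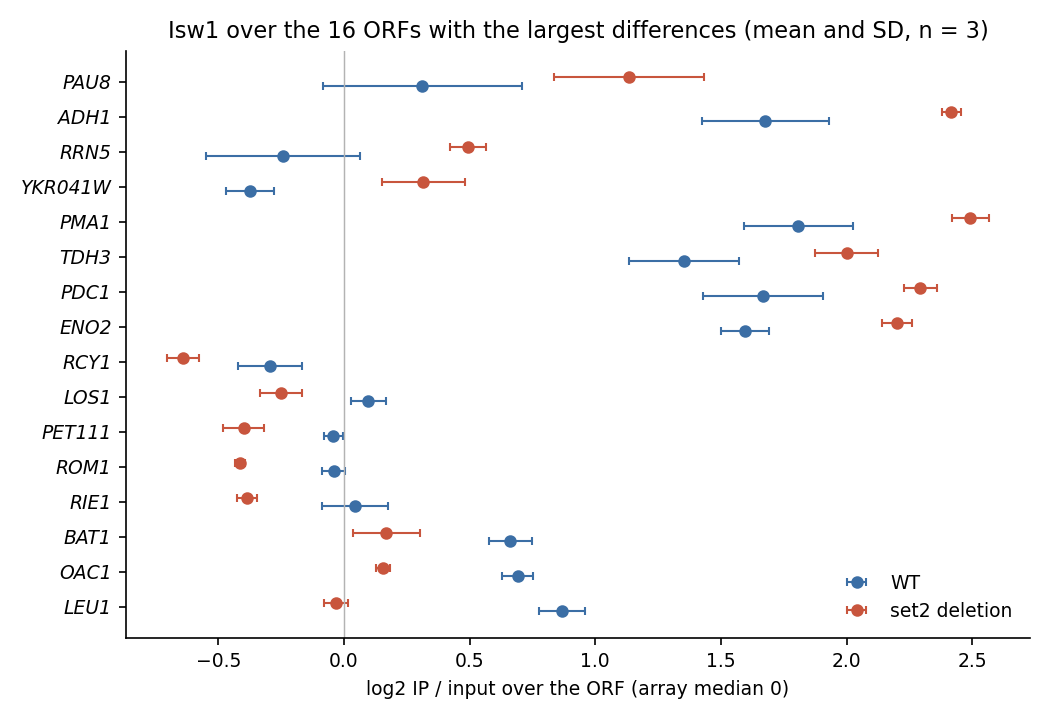
Log2 IP over input of Isw1 over the 16 ORFs with the largest rises and falls, mean and SD of 3 arrays, WT in blue and set2 in red. LEU1 lies at 0.87 in WT and -0.03 in set2.

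In all, 832 of 4502 ORFs passed the test in limma, 537 higher and 295 lower in set2, and 734 of 4712 promoters, 729 higher and 5 lower. The median promoter difference was 0.19. The largest promoter rises were at SPG4 (1.38), YLR162W (1.28), MRM1 (1.21), RRG1 (1.11) and YER137C (1.03), and the 5 falls were at YCR099C (-0.54), SAM50 (-0.48), YKR070W (-0.47), PGU1 (-0.36) and GLO4 (-0.35). The ORF split was 180 higher and 313 lower with quantile normalization (493 in all) and 364 higher and 495 lower with a correction for probe GC content. With quantile normalization 207 promoters passed. Single arrays moved the counts: ORFs numbered 503, 1416 and 226 without WT arrays 1, 2 and 3, and 250, 104 and 447 without set2 arrays 1, 2 and 3, while promoters numbered 76, 1639 and 2 without WT arrays 1, 2 and 3, and 0 (1116 at unadjusted p under 0.05) and 39 without set2 arrays 2 and 3.

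By gene list, Isw1 rose over cytoplasmic ribosomal protein ORFs, the structural proteins of the ribosome, where 52 of 77 rose and 0 fell over all ORFs tested and 69 rose when adjusted over the list alone. The mean difference was 0.27 (camera adjusted p = 1.61e-22), and it ended at 0.011 with quantile normalization (adjusted p = 0.28). The call was lost at adjusted p = 0.31 with an estimated correlation. Examples are RPL3 (0.57, -0.022 with quantile normalization), RPL10 (0.54), RPS14B (0.51) and RPP0 (0.50). Over glycolysis and fermentation genes, the enzymes from glucose to ethanol, 14 of 21 rose, 16 when adjusted over the list alone, with a mean of 0.33 (camera adjusted p = 1.62e-08) that ended at 0.05 with quantile normalization (adjusted p = 0.189). That call was lost at adjusted p = 0.502 with an estimated correlation. The list of Isw1, Chd1 and H3K36 pathway genes was lower (camera adjusted p = 0.0356, median -0.10, mean -0.04, adjusted p = 0.31 with an estimated correlation, 0.189 with quantile normalization, 0.0551 without replicate 1 and 0.218 without replicate 2). In it 3 of 26 rose, YNG1 (0.42) of the NuA3 acetyltransferase, IOC2 and LEO1 (0.28) of the Paf1 elongation complex, and 3 fell, among them SPT6 (-0.27), a histone chaperone of elongation. Adjusted over the list alone, 3 rose and 6 fell.

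The other lists did not pass camera for Isw1, although single members did. Of 51 amino acid biosynthesis genes 5 rose, such as ILV5 (0.54, -0.023 with quantile normalization) and LYS20 (0.31), and 2 fell, LEU1 among them (list adjusted p = 0.876, 5 and 2 adjusted over the list alone). Of 28 oxidative phosphorylation and TCA cycle genes 5 rose, such as MDH2 (0.44) and CYT1 (0.22) (list adjusted p = 0.0806, 5 adjusted over the list alone). Of 25 proteasome genes 6 rose, such as RPN10 (0.24) and SCL1 (0.23) (0.109, 6 adjusted over the list alone). Ribosome biogenesis had 4 rises, such as GAR1 (0.47) and DBP2 (0.36), and 4 falls among 42 (0.995, 5 and 4 adjusted over the list alone). Aminoacyl-tRNA synthetases had 1 rise, FRS2 (0.22), and 1 fall, CDC60 (-0.25), among 18 (0.876, 1 and 1 adjusted over the list alone). Stress and heat shock genes had 2 rises among 27, SSA2 (0.42) and SSB1 (0.27, -0.060 with quantile normalization) (0.876, 2 adjusted over the list alone). Meiosis and sporulation had 2 rises and 1 fall, SPO14 (-0.19), among 39 (0.876, 0 adjusted over the list alone). Pheromone response and mating had 2 rises, STE2 (0.29, -0.061 with quantile normalization) and BAR1 (0.23), and 1 fall, STE5 (-0.17), among 21 (0.995, 2 and 0 adjusted over the list alone). PAU8 was the 1 rise among 2 seripauperins (0.534, 1 adjusted over the list alone). Genes with known cryptic start sites inside the ORF (0 of 13, 0.876), galactose use (0 of 11, 0.995), the COS family (0 of 5, 0.995) and the 1 measured histone gene, CSE4 (0.995), had no limma call, over all ORFs or adjusted over the list alone.

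By gene length, over the shortest quartile of ORFs (334 to 948 bp) the mean set2 minus WT difference was 0.12, and over the longest quartile it was -0.07. The longest minus the shortest quartile was -0.15 in set2 and 0.03 in WT, a difference of -0.19 (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). An ORF value averages the probes from the gene start on, so short ORFs hold only probes near it. From 0 to 250 bp Isw1 was 0.04 in set2 and -0.12 in WT, and from 1000 to 1250 bp 0.11 and 0.20. Gene length and position along the gene can thus not be told apart here. By quartiles of WT Isw1 level, with the level taken from WT array 1 and the other 2 WT arrays compared, the corresponding difference was 0.04 (exact permutation p = 0.4).

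**Figure D4:**
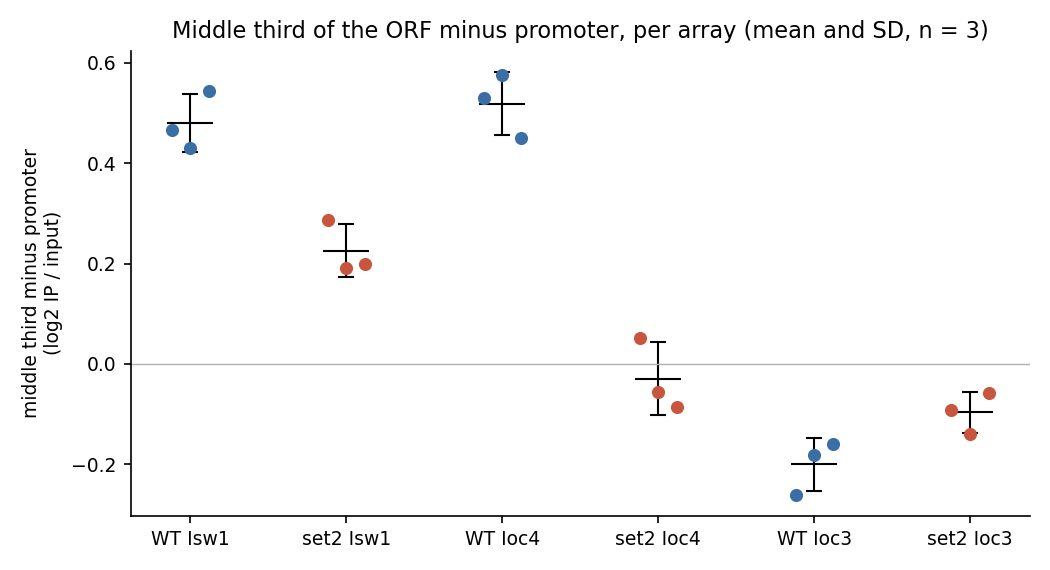
Mean log2 IP over input of the middle part of the ORF minus the promoter, 1 point per array, with the mean and SD of each group (n = 3). Arrays labelled Ioc4 lie between 0.45 and 0.58 in WT and between -0.09 and 0.05 in set2.

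The comparison of set2 with WT labelled Ioc4 asked whether a subunit of the Isw1b remodeler keeps its place on genes without Set2. In WT, arrays labelled Ioc4 were depleted over promoters (-0.32 ± 0.06 log2, SD, n = 3, mean over 2670 genes) and enriched over the middle part (0.20 ± 0.01). In set2 both were near the array median, at 0.03 ± 0.05 and 0.00. The set2 minus WT difference was 0.34 over promoters, 0.04 over the first part, -0.21 over the middle part and -0.14 over the last part. The middle part minus the promoter was 0.52 ± 0.06 in WT and -0.03 ± 0.07 in set2, a difference of -0.55 with an SE of 0.06, with 3 of 3 set2 arrays below all WT arrays. The exact permutation p was 0.1 for each of these except the first part (0.3), and 0.1 is the smallest that 3 against 3 arrays allow. Within scan session 1, where 1 set2 array was scanned with the 3 WT arrays, the difference was -0.47 (0.05 against 0.52). In the deposited table, where the columns of this name match the arrays of the other protein, it was 0.066. Across probes the set2 arrays correlated with each other at r of 0.30 to 0.44, against 0.60 to 0.73 among the WT arrays. The set2 array 2 correlated at 0.23 to 0.28 with the WT arrays of its label and at 0.30 to 0.49 with the arrays labelled Ioc3. These 3 set2 arrays are thus weakly concordant replicates, and no test was attached to these r.

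On arrays labelled Ioc4 long genes and genes rich in Isw1 had the lower set2 minus WT values. The longest minus the shortest quartile of ORFs was -0.11 in set2 and 0.10 in WT, a difference of -0.20. The quartile of ORFs with most WT Isw1 minus that with least was 0.38 in set2 and 0.75 in WT, a difference of -0.37. The exact permutation p was 0.1 for both, the smallest that 3 against 3 arrays allow. The second difference was -0.22 without the set2 array 2. For the first, short ORFs hold only probes near the gene start. From 0 to 250 bp the arrays labelled Ioc4 were 0.01 in set2 and -0.19 in WT, and from 1000 to 1250 bp 0.03 and 0.24. Length is thus not shown to act apart from position along the gene.

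No single ORF labelled Ioc4 passed the test: limma called 0 of 4478 ORFs and 0 of 4676 promoters in set2 against WT, with 742 and 870 at unadjusted p under 0.05, and the smallest adjusted p were 0.073 and 0.111. The median promoter difference was 0.34. With normexp background correction limma called 82 ORFs without loess and 0 with it (776 at unadjusted p under 0.05), without the set2 array 3 it called 30, without the set2 array 1 it called 1 ORF and 2 promoters, with at least 2 probes per promoter it called 6 promoters, and with the scan session as a block 0 of either (606 and 659 at unadjusted p under 0.05). Values of the genes named by rule were -0.29 for PMA1 (adjusted p = 0.668), -0.62 for IOC2 (0.705), 0.32 for ISW1 (0.464), -0.20 for CHD1 (0.53), -0.26 for IOC3 (0.636), 0.07 for IOC4 (0.939), -0.07 for FLO8 (0.848) and -0.03 for STE11 (0.932).

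Gene lists moved nonetheless. The same 3 WT arrays labelled Ioc4 enter this comparison, the difference of the set2 effects and that of both labels in WT. List results of these comparisons are thus not independent of each other. Values with the scan session as a block rest on set2 array 1 alone, the only set2 array in the session of the WT arrays. Meiosis and sporulation genes, which are silent in growing cells, rose as a list labelled Ioc4 (camera adjusted p = 4.28e-10, adjusted p = 0.0493 with an estimated correlation, 0.000113 with the scan session as a block). The mean was 0.25, with 33 of 39 members above 0 and 8 called higher when adjusted over the list alone. Values were 0.70 for HOP2 and 0.57 for REC8, both of meiotic chromosomes, 0.55 for LDS2 and 0.54 for SSP1. Aminoacyl-tRNA synthetase genes fell as a list (camera adjusted p = 6.77e-05, adjusted p = 0.0592 with an estimated correlation, 0.000113 with the session block). The mean was -0.33, with 16 of 18 below 0 and 7 called lower when adjusted over the list alone. Values were -0.73 for ILS1, -0.68 for SES1, -0.59 for FRS2 and -0.52 for MES1. Seripauperins rose with a mean of 0.46 over 3 genes (camera adjusted p = 0.00845, adjusted p = 0.11 with an estimated correlation, 0.0356 with the session block, 0.117 without replicate 3, 1 higher adjusted over the list alone), PAU8 at 0.60.

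Other lists also fell with camera labelled Ioc4 and lost the call with the session block, which again rests on set2 array 1 alone. They were ribosome biogenesis (mean -0.19, camera adjusted p = 0.00845, adjusted p = 0.17 with an estimated correlation, 0.0803 with the session block, 0.109 without replicate 2, NSR1 -0.62), amino acid biosynthesis (mean -0.15, camera adjusted p = 0.0422, adjusted p = 0.158 with an estimated correlation, 0.577 with the session block, 0.0595 with MAD scaling, 0.0554 with the GC correction, 0.0909 without replicate 2 and 0.22 without replicate 3, 1 higher and 4 lower of 53 adjusted over the list alone) and ribosomal proteins (mean -0.24, camera adjusted p = 0.0322, adjusted p = 0.625 with an estimated correlation, 0.271 with the session block). Ribosomal proteins turned upward without replicate 2 (adjusted p = 0.0909), and RPP0 had a value of -0.74. Among amino acid genes ILV2, the acetolactate synthase, had -0.81 (limma adjusted p = 0.073) and LEU4, an isopropylmalate synthase, -0.97 (adjusted p = 0.113). Not past the test were glycolysis (0.282, 1 higher and 1 lower adjusted over the list alone), oxidative phosphorylation (0.0986, 2 lower), stress and heat shock (0.291, 1 and 1), the COS family (0.0518, 1 higher), galactose use (0.511, 1 lower), histones (0.511), cryptic start sites (0.511), proteasome (0.375), pheromone response (0.491) and the Isw1, Chd1 and H3K36 pathway (0.491), the last 5 with 0 calls adjusted over the list alone.

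The comparison of set2 with WT labelled Ioc3 asked the same of the Isw1a subunit. Arrays labelled Ioc3 were highest over promoters, at 0.23 ± 0.02 log2 (SD, n = 3, mean over 2670 genes) in WT and 0.20 ± 0.04 in set2. Over the middle part they were 0.03 in WT and 0.10 in set2. The middle part minus the promoter was -0.20 ± 0.05 in WT and -0.10 ± 0.04 in set2, a difference of 0.10 with an SE of 0.04 (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). By region the difference was -0.03 over promoters (exact permutation p = 0.2), 0.09 over the first part and 0.08 over the middle part (0.1 each) and 0.01 over the last part (0.4). Within scan session 4, with 2 arrays of each genotype, the middle part minus the promoter differed by 0.06. In the deposited table, where the columns of this name match the arrays of the other protein, the difference was -0.49. Without the set2 array 3, which kept SET2 signal in its input, the difference was 0.085. By quartiles of ORF length and of WT Isw1 level the differences were 0.04 and -0.12 (exact permutation p = 0.4 and 0.5).

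Labelled Ioc3, limma called 0 of 4478 ORFs and 0 of 4676 promoters, with 183 and 191 at unadjusted p under 0.05 and smallest adjusted p of 0.411 and 0.835. With the scan session as a block limma also called 0 of each (137 and 118 at unadjusted p under 0.05), and without the WT array 1 it called 1 ORF. IOC3 was 0.90 ± 0.56 in set2 and 1.54 ± 0.49 in WT (-0.64, adjusted p = 0.889), IOC2 differed by -1.27 (0.889), PMA1 by -0.23 (0.917), ISW1 by 0.10 (0.953), CHD1 by 0.02 (0.984), IOC4 by 0.25 (0.916), FLO8 by 0.30 (0.889) and STE11 by 0.11 (0.917). Ribosomal protein genes fell as a list (mean -0.28, 69 of 77 below 0, camera adjusted p = 7.15e-18, adjusted p = 0.383 with an estimated correlation, 0.0033 with the session block). Glycolysis and fermentation genes also fell (mean -0.26, camera adjusted p = 8.82e-08, adjusted p = 0.383 with an estimated correlation, 0.0017 with the session block). Examples are RPL6A (-0.82), RPS7A (-0.82), HXK2 (-0.52) and FBA1 (-0.47), none of them past the test alone. Other lists had camera adjusted p of 0.0808 (amino acid biosynthesis, which was lower with the GC correction at adjusted p = 0.0269 and without replicate 3 at 0.0277), 0.108 (ribosome biogenesis, aminoacyl-tRNA synthetases and galactose use), 0.288 (histones, meiosis and sporulation, stress and heat shock), 0.338 (Isw1, Chd1 and H3K36 pathway, which was lower with the session block at adjusted p = 0.0245), 0.402 (COS family), 0.409 (seripauperins), 0.633 (proteasome), 0.879 (oxidative phosphorylation and pheromone response) and 0.998 (cryptic start sites). In all 16 lists 0 members passed when adjusted over the list alone.

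**Figure D5:**
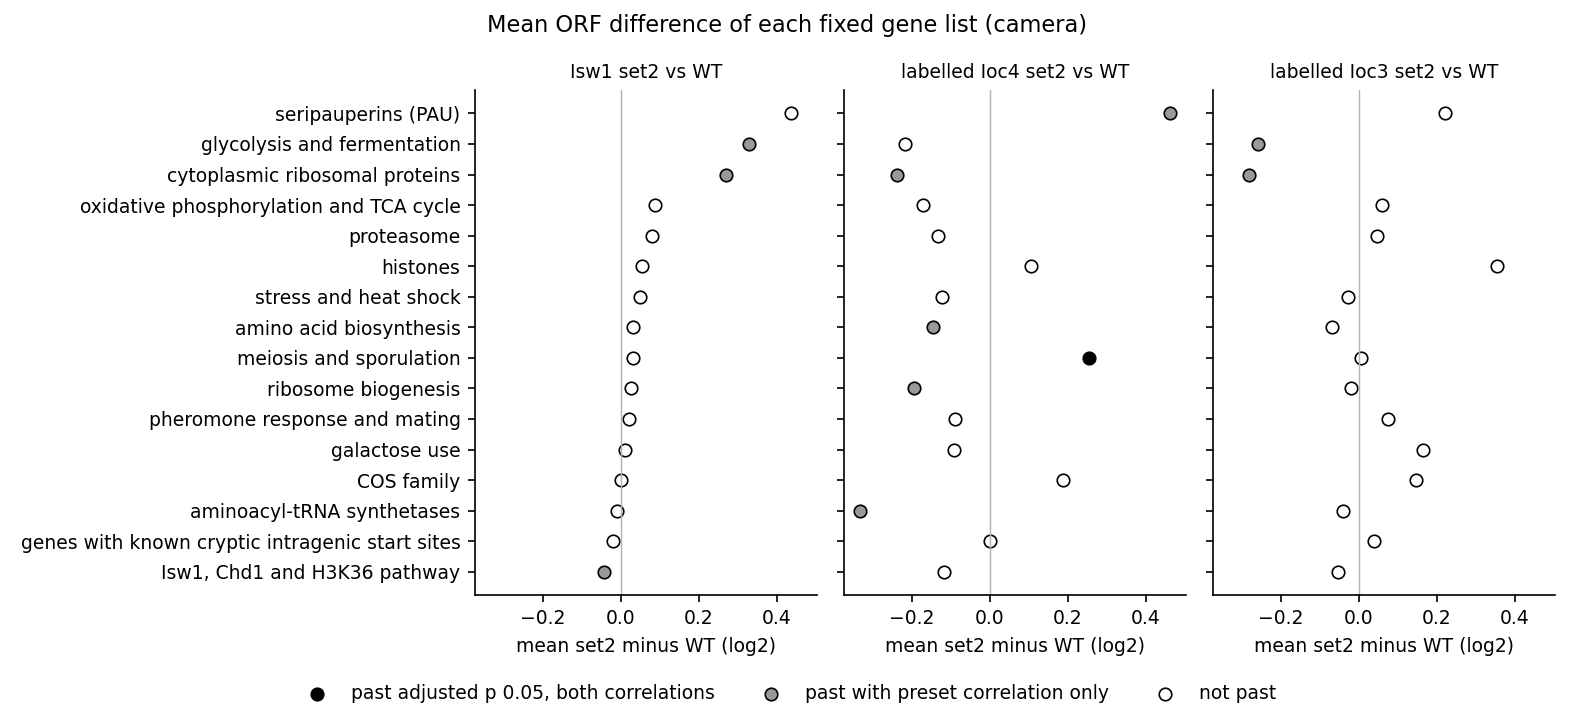
Mean log2 set2 minus WT difference over the ORFs of each of 16 gene lists for Isw1 and for the arrays labelled Ioc4 and Ioc3; black points passed camera with both correlations, grey points with the preset correlation only, open points with neither. Ribosomal proteins lie at 0.27 for Isw1 (0.011 with quantile normalization) and at -0.24 and -0.28 labelled Ioc4 (upward in camera without replicate 2) and Ioc3.

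The set2 effects labelled Ioc4 and Ioc3 differed along genes. The effect labelled Ioc4 minus that labelled Ioc3 was 0.37 over promoters (permutation of genotypes within each label, p = 0.01), -0.05 over the first part (0.49), -0.28 over the middle part (0.005) and -0.15 over the last part (0.02). For the middle part minus the promoter it was -0.65 with an SE of 0.07 (permutation p = 0.005, the smallest possible). This permutation leaves out the scan session, which was 1 for all WT arrays labelled Ioc4 and 1, 2 and 3 for their set2 arrays. Genotype and session are thus partly confounded. With the session block below, set2 array 1 alone stands for set2 labelled Ioc4. For single features limma called 0 of 4478 ORFs and 0 of 4676 promoters (565 and 634 at unadjusted p under 0.05), also with the scan session as a block (386 and 374), and 4 promoters without the set2 array 1 labelled Ioc4. In the lists, meiosis and sporulation genes rose more labelled Ioc4 (mean 0.25, camera adjusted p = 1.38e-08, adjusted p = 0.0786 with an estimated correlation, 5.48e-05 with the session block, HOP2 0.98, MER1 0.95). Aminoacyl-tRNA synthetases fell more (mean -0.29, camera adjusted p = 0.0491, adjusted p = 0.435 with an estimated correlation, 0.00502 with the session block, 0.0785 with MAD scaling, 0.0816 with the GC correction, 0.0756 to 0.181 without each replicate, FRS2 -0.77, ILS1 -0.71). Ribosomal proteins were higher than other genes (mean 0.045, camera adjusted p = 0.0178, adjusted p = 0.692 with an estimated correlation, 0.985 with the session block, 0.157 with the GC correction, 0.957 without replicate 1, 0.221 without replicate 3). The other lists had adjusted p of 0.13 (glycolysis, which was higher with the session block at adjusted p = 0.0146 and without replicate 2 at 0.00562), 0.158 (seripauperins, higher without replicate 2 at 0.0109), 0.208 (oxidative phosphorylation and galactose use), 0.349 (ribosome biogenesis), 0.381 (proteasome and COS family), 0.597 (pheromone response), 0.672 (amino acid biosynthesis), 0.696 (cryptic start sites), 0.789 (histones), 0.871 (stress and heat shock) and 0.95 (Isw1, Chd1 and H3K36 pathway). Adjusted over the list alone, 2 aminoacyl-tRNA synthetases and 2 oxidative phosphorylation genes were lower, 2 stress genes and 1 seripauperin higher and 1 stress gene lower.

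The comparison of arrays labelled Ioc4 with those labelled Ioc3 in WT cells asked where a subunit of each remodeler sits. The signal labelled Ioc4 minus that labelled Ioc3 was -0.54 log2 over promoters, 0.18 over the middle part and 0.07 over the last part (3 arrays each, exact permutation p = 0.1, the smallest possible). Over the first part the difference was -0.09 (exact permutation p = 0.2). The middle part minus the promoter differed by 0.72 with an SE of 0.05, with 3 of 3 arrays apart. In the deposited table, where both protein names are exchanged, the difference was -0.65. No scan session held WT arrays of both labels, so session and label cannot be told apart among these 6 arrays. A fixed session block links them only through set2 arrays 1 and 2 labelled Ioc4 and WT array 1 labelled Ioc3. Of these, the set2 array 2 had 83.9% of IP spots above background. Calls lost or turned with that block thus rest on single arrays. Among ORFs, SSC1 (1.01), the mitochondrial Hsp70, SSO1 (0.88), a plasma membrane SNARE, URA4 (0.94), SLY41 (0.93), RPL19A (0.92), ASN2 (0.89), SUR1 (0.87) and NIP1 (0.86), a translation initiation factor subunit, were higher labelled Ioc4. With the scan session as a fixed block these 8 lost the call and RPL19A turned to -0.16. SSC1 was 1.06 ± 0.11 against 0.05 ± 0.14 (chromosome 10, probes 519409 to 521303, limma adjusted p = 0.00859). IOC3 itself was higher labelled Ioc3, 1.54 ± 0.49 against 0.01 ± 0.15 (chromosome 6, probes 170078 to 172186, limma adjusted p = 0.0158), as was IOC2, 4.97 ± 1.51 against 1.86 ± 1.64 (adjusted p = 0.0356). For IOC2 the arrays overlapped: WT array 1 was 3.76 labelled Ioc4 and 3.68 labelled Ioc3. WT arrays 2 and 3 labelled Ioc4 were 0.85 and 0.97. IOC2 ranked 1 to 4 of 4478 ORFs on the WT arrays labelled Ioc3, but also 1 on WT array 1 labelled Ioc4. Whether the values over IOC2 and IOC3 measure binding was not tested. ANK1 (-1.58), SND2 (-1.33), POF1 (-1.33), TIS11 (-1.29) and SCO1 (-1.25) were lower labelled Ioc4. URA3 and LEU2 also passed, but their input DNA was missing on 1 or both sides, so that their ratios do not measure binding. Of the 26 ORFs named in this comparison that passed, URA3 and LEU2 included, 1, ANK1, kept its call with that block, 23 lost it and 2 turned. ISW1 (-0.15, adjusted p = 0.689), CHD1 (0.18, 0.524), IOC4 (-0.49, 0.387), FLO8 (0.41, 0.112), STE11 (-0.04, 0.882) and PMA1 (0.55, 0.298) did not pass.

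Among promoters, limma called 477 of 4676 promoters, 476 of them lower labelled Ioc4, such as NGL3 (-3.12), SEC31 (-2.95), VPS38 (-2.78), STM1 (-2.60) and YFR006W (-2.34), and RCR2 (1.20) as the 1 higher. With the session block SEC31 and YFR006W kept the call and the other 4 lost it. Limma called 207 of 4478 ORFs, 88 higher and 119 lower. The ORF split was 288 higher and 162 lower with normexp background correction without loess, 111 and 144 with loess, 113 and 63 with medians over probes, and 293 and 84 without centring. Array medians before centring were -0.04 to -0.01 in WT labelled Ioc4 and -0.16 to -0.13 in WT labelled Ioc3. With the scan session as a fixed block 3 ORFs and 26 promoters were called, and without centring 4 promoters. ORF counts were 23, 1 and 63 without WT arrays 1, 2 and 3 labelled Ioc4 and 52 and 15 without WT arrays 2 and 3 labelled Ioc3, and promoter counts 3, 1, 75, 78 and 65 in the same order.

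Gene lists also differed between both labels in WT. This comparison shares its WT arrays labelled Ioc4 with that of set2 against WT labelled Ioc4. Each list that passed camera in both had opposite signs in them. Means were 0.25 in set2 against WT and -0.37 here for meiosis and sporulation, and -0.33 and 0.37 for aminoacyl-tRNA synthetases. Such mirrored lists do not count as separate findings. With the session block the lists, too, are compared through single arrays only, the set2 array 2 labelled Ioc4 among them. Labelled Ioc4, meiosis and sporulation genes were lower (mean -0.37, camera adjusted p = 4.81e-09, adjusted p = 0.033 with an estimated correlation, 0.0793 with the session block), with 6 of 39 lower, 9 adjusted over the list alone, such as MEK1 (-0.98), MER1 (-0.92) and MEI4 (-0.87). Aminoacyl-tRNA synthetases were higher (mean 0.37, camera adjusted p = 7.1e-06, adjusted p = 0.033 with an estimated correlation, 0.162 with the session block), with 6 of 18 higher, 8 adjusted over the list alone, such as SES1 (0.69, -0.081 with the session block), GRS1 (0.63), THS1 (0.62) and VAS1 (0.59). Proteasome genes (camera adjusted p = 0.00301, adjusted p = 0.033 with an estimated correlation, 0.748 with the session block, 2 higher, 5 adjusted over the list alone) were higher, such as RPN5 (0.67) and RPT3 (0.63). So were ribosome biogenesis genes (mean 0.25, camera adjusted p = 1.73e-05, adjusted p = 0.0427 with an estimated correlation, 0.757 with the session block, 1 higher, DIP2 at 0.64) and oxidative phosphorylation genes (camera adjusted p = 0.0133, adjusted p = 0.0649 with an estimated correlation, 0.748 with the session block, 0.0532 without replicate 1, 2 higher). Ribosomal proteins were higher (mean 0.39, camera adjusted p = 1.2e-07, adjusted p = 0.429 with an estimated correlation, 4 of 77 higher) but lower than other genes with the session block (adjusted p = 9.35e-13). Seripauperins were lower (camera adjusted p = 0.0466, adjusted p = 0.141 with an estimated correlation, 0.103 with the session block, 0.0547 with MAD scaling, 0.0624 with the GC correction, 0.084 without replicate 1, 0.13 without replicate 3, 1 lower). Not past the test were amino acid biosynthesis (0.0506, 3 higher and 1 lower, 4 and 2 adjusted over the list alone), stress and heat shock (0.0876, 1 lower), glycolysis (0.133, 1 lower, 2 higher and 1 lower adjusted over the list alone, lower with the session block, adjusted p = 2.97e-06), the COS family (0.152, 1 lower), cryptic start sites (0.343, 1 lower adjusted over the list alone), histones (0.69), pheromone response (0.761, 2 higher and 1 lower adjusted over the list alone), galactose use (0.959) and the Isw1, Chd1 and H3K36 pathway (0.959, 2 lower). In lists given 1 count, it was the same adjusted over the list alone. Of all 80 tests of a list in a comparison, 21 passed with the preset correlation and 5 with an estimated one.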

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

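The tests of explanations in this part were chosen after the results they weigh had been seen, and the counts over other splits of the arrays were planned.

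Set2 effects labelled Ioc4 and Ioc3 drew attention because a test of their difference passed. The effect labelled Ioc4 minus that labelled Ioc3 was 0.37 over promoters, -0.28 over the middle part of the ORF, -0.15 over the last part and -0.65 for the middle part minus the promoter. In the gene lists it was 0.25 for meiosis and sporulation, -0.29 for aminoacyl-tRNA synthetases and 0.045 for ribosomal proteins. These 3 lists passed camera with the preset correlation only, with adjusted p = 0.0786, 0.435 and 0.692 with an estimated correlation.

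The set2 arrays labelled Ioc4 lacked the contrast between the middle part and the promoter that the WT arrays had. A uniformly weaker IP would shrink every contrast alike if no other signal remained on the array. The set2 arrays kept 50.6% of the WT contrast between the ORFs with most and least Isw1 and -5.71% of that between the middle part and the promoter. The gap averaged 56.3 points (SE 21.0) and was 55.1, 20.6 and 93.4 on arrays 1, 2 and 3. Array 2 kept 9.81% of the first contrast. Against the same WT contrasts, the arrays labelled Ioc3 also had positive gaps, from 27.3 to 106.5 points. A positive gap is thus not specific to these set2 arrays. The test therefore cannot decide on a weaker IP, which stays open. Scan session stays open, since 1 set2 array shared a session with the WT arrays, and with the session as a block the difference was -0.47 (SE 0.06); the loss of Set2 also stays open as a hypothesis.

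Columns of the deposited table for Ioc3 and Ioc4 matched the scanner arrays of the other protein. Processing differences between the sources are argued against by the highest r of a column with the array of its own label, 0.445, which was below the lowest best match with the other protein, 0.82. Labels exchanged in 1 of the 2 sources are a possible explanation, with 12 of 12 columns matching the array of the other protein with the same background and number. Which source carries the exchange cannot be told from these values, and no biological explanation was tested.

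Isw1 in set2 was flatter along genes and higher over ribosomal protein ORFs. A distribution of log ratios that differs between arrays is argued against for the flatter profile, which was -0.24 (SE 0.04) after quantile normalization, and so is the GC content of the probes, with -0.27 (SE 0.04) after its correction. The ribosomal protein rise went from 0.27 (SE 0.03) to 0.011 (SE 0.022) after quantile normalization, which is consistent with such a distribution, while a gain of Isw1 on the most occupied genes stays open, since the normalization would remove it too. Array batch stays open for both, because 0 scan sessions are known to hold Isw1 arrays of both genotypes.

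Input signal drew attention at marker genes, where no comparison tests the input itself, although URA3 and LEU2 ratios are among the ORFs reported. It was 0.18 log2 at HIS3 in the WT arrays labelled Ioc3, where the other groups ranged from -5.38 to -4.43. At URA3 it was 0.60 in the WT arrays labelled Ioc4, where the other groups ranged from -7.26 to -1.28. On the set2 array 3 labelled Ioc3 it was -2.61 at LEU2, -3.44 at MET17 and -2.32 at SET2, each above the other arrays of its group. At SET2 this is 20.0% of the array median, at LEU2 16.4% and at MET17 9.22%, against at most 2.98%, 0.62% and 0.479% on arrays 1 and 2. The array was also higher at HIS3 (12.8%, against at most 2.83%) and at URA3 (6.57%, against at most 1.23%). At YCR108C, which was low on all arrays shown, it was not higher (1.42%, against 1.93% and 1.30%). Whether DNA of other cells was mixed into this array was not tested and stays open, so that the set2 group labelled Ioc3 may not be pure; without the array the middle part minus the promoter differed by 0.085 (0.10 with it). Input at HIS3 thus differed between WT and set2 labelled Ioc3, at URA3 between WT and set2 labelled Ioc4, and at both between the labels in WT. What this adds to those comparisons was not tested.

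For the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 832 and 0 for Isw1 ORFs, 734 and 13 for Isw1 promoters and 3 and 5 for Isw1 gene lists. Labelled Ioc4 they were 0 and 2 for ORFs (742 at unadjusted p under 0.05 in limma), 0 and 2 for promoters (870) and 6 and 5 for lists. Labelled Ioc3 they were 0 and 0 for ORFs (183) and promoters (191) and 2 and 3 for lists. For both labels in WT they were 207 and 0, 477 and 0, and 7 and 6. For the difference of the set2 effects, the real counts of ORFs and promoters were 0 in limma (565 and 634 at unadjusted p under 0.05), so that 100 of 100 splits give as many whatever the data, and the count says nothing (highest other 1 and 14). For its gene lists 43 of 100 splits gave as many (3, highest other 8), so chance cannot be excluded.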

How the results depend on the processing

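The GC correction, the fits without 3 doubted arrays or within a session, and the alternatives for the gene lists (except the estimated correlation and the replicate block), the quartiles and the difference of the set2 effects along genes were chosen after the data were seen; the others were planned. Of 380 alternatives for the results of the comparisons, 324 stayed within their limits, 52 moved and 4 reversed. All 4 reversals arose with the deposited table, where the names Ioc3 and Ioc4 are exchanged. For single named genes 3162 of 3924 stayed, 430 lost and 41 gained a call, 253 moved and 38 reversed, and for gene lists 651 of 720 stayed. Of those 38, 26 ORFs and 6 promoters of both labels in WT turned with the deposited table. Except in the deposited table, the middle part minus the promoter kept its sign, at -0.59 to -0.50 for set2 labelled Ioc4, 0.07 to 0.13 labelled Ioc3, 0.63 to 0.75 between both labels, -0.70 to -0.58 for the difference of the set2 effects and -0.28 to -0.22 for Isw1. In the deposited table the first 4 of these were 0.066, -0.49, -0.65 and 0.55, and the protein names of its columns are exchanged relative to the scanner files. Matched by array instead of by name, its set2 minus WT differences were -0.49 labelled Ioc4 and 0.066 labelled Ioc3. Both have the sign found with the scanner files. Within a scan session the difference was -0.47 labelled Ioc4 and 0.056 labelled Ioc3, outside these ranges. With the deposited columns under their own names, 1 ORF passed for set2 against WT named Ioc4, whose columns match the arrays labelled Ioc3 here. For both names in WT 119 ORFs and 14 promoters passed, and each named gene turned. The exchange of names alone would turn these signs, so the turns say nothing of the processing. Values over ORFs were SSC1 -0.64, URA4 -0.85, SLY41 -0.61, RPL19A -0.61, ASN2 -0.39, SSO1 -0.73, SUR1 -0.67, NIP1 -0.74, RPL26A -0.78, SES1 -0.46, GRS1 -0.53, THS1 -0.46, VAS1 -0.40, URA3 4.48, LEU2 2.54, ANK1 1.46, IOC3 1.39, SND2 1.19, POF1 1.22, TIS11 1.17, SCO1 1.20, IOC2 3.08, GAS4 1.06, MEK1 0.88, MER1 0.75 and MEI4 0.95, where URA3 and LEU2 lack input DNA and their ratios do not measure binding. At promoters they were RCR2 -1.21, NGL3 2.95, SEC31 2.56, VPS38 2.56, STM1 2.46 and YFR006W 2.00. Below, the cause was not tested except where arrays or probes are fewer. Normexp without loess called 82 ORFs for set2 labelled Ioc4 and 450 for both labels in WT (207 as reported). That comparison had 102 ORFs and 279 promoters with MAD scaling, 377 and 4 without centring, 137 and 265 with the replicate block, 3 and 26 with the session as a fixed block, 1 and 1 as a random block, 30 and 2 in a fit of its own arrays, and 52 and 78 without the doubted arrays. With the fixed session block, which links both labels in WT through single arrays only, RPL19A was -0.16 and SES1 -0.081. With it ribosomal proteins turned lower, with a camera p of 5.84e-14 (adjusted p = 9.35e-13). For set2 against WT labelled Ioc4 and Ioc3 limma called 0 ORFs and promoters with and without the session block, so that no call was there to lose; labelled Ioc4 those at unadjusted p under 0.05 went from 742 to 606 and from 870 to 659. For Isw1 the block could not be fitted, as the sessions of the WT arrays are unknown. At least 2 probes gave 6 promoters for set2 labelled Ioc4, and MAD scaling 1 ORF for the difference of the set2 effects. For Isw1, quantile normalization gave 493 ORFs and 207 promoters and turned RPL3 (-0.022), SSB1 (-0.060), ILV5 (-0.023) and STE2 (-0.061), medians over probes gave 510 ORFs and the replicate block 1146 promoters. With the replicate block the pathway list lost its call for Isw1 (adjusted p = 0.0622), and the COS family labelled Ioc4 (0.0426) and amino acid biosynthesis in WT (0.0489) gained one. Lists also gained a call without replicate 1 (labelled Ioc4 glycolysis and the COS family, adjusted p = 0.0139 each, and in WT glycolysis, 0.00472, and amino acid biosynthesis, 0.0341), without replicate 2 (oxidative phosphorylation for Isw1, 0.0263, and amino acid biosynthesis in WT, 0.0263) and with input probes above background only (amino acid biosynthesis in WT, 0.0161). An estimated correlation left 5 of 21 gene lists, and without replicate 2 ribosomal proteins labelled Ioc4 turned higher (camera p = 0.0227, adjusted p = 0.0909), where camera p over the replicates left out was 9.83e-11 to 0.0227. Leaving out each array in turn gave 104 to 1416 Isw1 ORFs and 0 to 1639 promoters (limma, 1116 at unadjusted p under 0.05 at 0), 0 to 30 ORFs and 0 to 2 promoters for set2 labelled Ioc4, 0 to 1 ORFs labelled Ioc3, 1 to 308 ORFs and 1 to 612 promoters for both labels in WT, and 0 to 4 promoters for the difference of the set2 effects. A lone array left in a fit is assumed to vary like the others. Signal over background limits the WT array 2 labelled Ioc3 (73.5% of IP spots above it) and the set2 array 2 labelled Ioc4 (83.9%).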

Other observations

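The tests in this part were chosen after the results they follow had been seen. LEU1, OAC1 and BAT1, the ORFs where Isw1 fell most in set2, are known targets of Leu3, the activator of branched-chain amino acid genes, so a hypothesis is that Isw1 may fall over genes bound by Leu3. Over 4 other targets the set2 minus WT difference was -0.03 for LEU4, -0.13 for ILV2, 0.54 for ILV5 and -0.06 for GDH1, with a mean of 0.080 (SE 0.15). For ILV3 and LEU9, not in that mean, it was -0.16 (limma adjusted p = 0.076) and 0.022, and over all 6 the mean was 0.031 (SE 0.11). The spread over these genes was too wide for the test to tell, and ILV5 turned to -0.023 with quantile normalization.

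A further hypothesis was that ORFs that gained Isw1 in set2 may gain signal labelled Ioc4, relative to those that lost it, more than labelled Ioc3. The gap between 531 ORFs that gained and 293 that lost Isw1 was 0.45 ± 0.20 in set2 and 0.29 ± 0.03 in WT labelled Ioc4, and 0.36 ± 0.03 and 0.44 ± 0.17 labelled Ioc3 (SD, n = 3). The difference between both changes was 0.24 (permutation of genotypes within each label, p = 0.145), which leaves the hypothesis open.

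Signal over the ORFs of the complex subunits differed by gene. IOC2 ORF values were 2.59 to 6.62 log2 on the arrays labelled Ioc3 and 0.85 to 3.76 on those labelled Ioc4. Among 4478 ORFs IOC2 ranked 1 to 4 on each array labelled Ioc3. Labelled Ioc4 it ranked 1 on WT array 1, 4 on set2 array 2 and 89 to 176 on the other arrays. Whether values this high and this uneven between replicates measure binding was not tested. IOC3 values were 0.30 to 2.07 labelled Ioc3 and -0.33 to 0.13 labelled Ioc4, and IOC4 values -0.05 to 1.81 labelled Ioc3 and -0.07 to 0.32 labelled Ioc4.

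Across 4472 ORFs the correlation with the mean of WT Isw1 was 0.652 to 0.793 on the WT arrays labelled Ioc4 and 0.0358 to 0.45 on the WT arrays labelled Ioc3. It was 0.117 to 0.669 and 0.0322 to 0.192 on the set2 arrays. Genes are not independent replicates, and no test was attached.

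Input signal at LEU2 was -8.08 ± 0.44 log2 in WT labelled Ioc4 and -8.46 ± 0.63 labelled Ioc3, and at MET17 -7.45 ± 0.23 and -7.45 ± 0.52, so that ratios over these genes lack input DNA. Of the genes with low input signal only SET2 was left out. Means, counts and camera p of a gene list, such as amino acid biosynthesis, may thus include such ratios.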
